A study of Homo sapiens with 8 samples.

How the data were processed

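RNA sequencing libraries were made from LNCaP cells after 4 hours of treatment in 4 groups of 2 libraries, with strand-specific TruSeq RNA kits per the extract protocol. The labels give total RNA as the molecule and the series design speaks of mRNA profiles. The deposited values are a signal per gene and library, namely gene read counts that the authors divided by 1 size factor per library, with STAR, HTSeq and DESeq2 and the builds hg19 and GRCh37 named in the submitters' processing notes. Versions, the roles of the tools, the annotation, filters and the strand used for counting are not given in the sources used here. The labels number the replicates, and nothing in them says that equal numbers share a culture or a day.

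Dividing each deposited column by its own smallest step gave whole read counts for 100% of values within a tolerance of 0.01 in every library, so the coverage of each library could be recovered as counts. The deposited factors were 0.972 to 0.987 times those that DESeq2 computed from the recovered counts. Replicates differed by far more than counting error, with a chi-square per degree of freedom of 28.1 in control, 23.7 with OSMI-2, 36.5 with AT7519 and 23.2 with the combination, so no library repeats another. The table held 55737 genes, of which 22359 were 0 in every library, and 28 lines without a gene name were dropped. Of the symbols, 33909 matched GENCODE release 29 directly, 1378 matched by an older symbol, and 20450 did not match. GENCODE was used only for gene types, spans, exon numbers and overlaps by symbol, so no positions are given, as the values rest on an older build. Of tested genes, 15823 (81.6%) had a gene type.

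Genes with a mean of at least 10 normalised counts over the 8 libraries were tested, 19393 in all, which held 99.971% of the deposited counts. Values were taken to log2 after adding a pseudocount of 1. One limma model (version 3.58.1, R 4.3.3) with a mean-variance trend was fitted to the 4 group means, with 4 residual and 10.1 prior degrees of freedom. The comparisons were OSMI-2, AT7519 and the combination against control, the combination against AT7519 and against OSMI-2, and the interaction of both agents. The p-values were two-sided and adjusted by the Benjamini-Hochberg method over the genes of each comparison, and genes with an adjusted p below 0.05 were called. A called gene is said to rise or fall, and genes that were not called are given by their values. Fold changes are 2 to the power of the fitted log2 change, so they can differ from the ratio of the group means printed beside them.

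The 27 gene lists were written down from general knowledge and tested in each comparison with camera (limma) at a preset correlation of 0.01, adjusted over the 27 lists. Estimated correlations and fry were run beside it. With an estimated correlation camera tests on the 4 residual degrees of freedom, so it has little power here. Camera compares a list with all other genes, whereas fry asks whether its genes move, on balance, one way. Results are given for each list described with a count of members called over all genes and of members called when p-values were adjusted over the list alone. One listed symbol, PECAM1, was not found in the table.

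Named genes were chosen by a fixed rule: in each comparison the 8 largest rises and 8 largest falls among called genes with a mean of at least 50 normalised counts and a proper symbol, with both libraries of 1 group above both of the other in the comparisons of 2 groups, then for each list described up to 2 called members with the largest rise and 2 with the largest fall, and always OGT, MGEA5, CDK9, HEXIM1, MYC, MCL1, CCND1, KLK3 and CDKN1A. Fewer genes are named than the rule gives, mainly because some lay near the floor or for brevity; which to leave out was decided after their values were seen. Besides these, 3 genes and 1 list that the rules give are not reported here. The always-named genes are given in part for the combination against OSMI-2. Alternatives for lists in that last comparison were tabulated only for 5 lists: immediate early genes, cholesterol genes, splicing factors, ribosomal proteins and zinc finger genes.

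A sum of normalised counts can be shared between overlapping genes or near-identical ones. On the same strand, EID3, LRRC70, RPA4, FUT4, RPS10, RPS15A, NDUFA9, CAPN3, RRS1, SNORD14A, SNORD37 and SNORD59A lie within or across a protein-coding gene. A protein-coding gene on the other strand overlaps ALDH1L2, ARG1, CCDC87, CCND1, CCNE2, CLK3, DMGDH, DNAJB1, DNAJB9, FOSB, HSP90AA1, KRT8, MCM7, MEPCE, NDUFA4L2, PCK2, PLK1, PPP1R10, BRD2 and ZNF382, which matters if counting ignored the strand. Overlaps with non-coding genes and pseudogenes, among them those of MCL1, NDUFV2 and BTG1 on the same strand, are not listed in full. UGT2B10, PRSS1, KLK2, KLK3, HSP90AA1, ribosomal proteins and histones have close relatives or pseudogenes with which reads can be shared.

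Alternatives changed 1 choice at a time: the pseudocount (0.5 and 5), the filter (none, and a mean of at least 50), the scale (equal totals, equal upper quartiles, quantile normalisation, and equal geometric means of the mitochondrially encoded mRNAs), limma without the trend or with robust shrinkage, a fit to the compared groups only, the replicate number as a block, each library left out in turn, and a minimum change of 1 on the log2 scale. Further tests changed several choices together, namely edgeR (version 4.0.16, quasi-likelihood with TMM) and DESeq2 (version 1.42.0, with its own filter) on the recovered reads. Where 1 library was left out, the lone library of its group was assumed to vary like the others. The edgeR test called 667 genes for OSMI-2, 10420 for AT7519, 10541 for the combination against control, 3489 against AT7519, 10665 against OSMI-2 and 184 for the interaction. With groups of 2, outliers and other splits of the libraries were not tested.

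The test was tried on simulated counts with the depths and dispersions of these libraries, with 50 genes at each fold and no other effect. For OSMI-2 against control it recovered 38%, 68%, 88% and 94% of genes changed 1.5, 2, 4 and 8-fold, with 6 false calls among 150. For AT7519 against control it recovered 36%, 74%, 84% and 98% (7 false of 153), for the combination against control 54%, 68%, 88% and 98% (7 of 161), against AT7519 40%, 74%, 84% and 98% (12 of 160), against OSMI-2 56%, 66%, 88% and 96% (11 of 164), and for the interaction 26%, 52%, 82% and 90% (8 of 133). Camera called 3 of 3 lists moved by 0.5 on the log2 scale and 0 of 24 other lists in the simulated counts. Genes were simulated independently of each other, so this does not measure false calls where genes of a list move together. The estimated correlation of G1/S and DNA replication genes, for example, was 0.736.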

Results

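LNCaP is a human prostate cancer cell line, grown from a lymph node metastasis, that secretes prostate-specific antigen. Gene expression was measured by RNA sequencing in LNCaP cells treated for 4 hours with a control, with 40 µM OSMI-2, with 0.5 µM AT7519, or with both together. OSMI-2 inhibits O-GlcNAc transferase (OGT), the enzyme that attaches N-acetylglucosamine to nuclear and cytosolic proteins. AT7519 inhibits several cyclin-dependent kinases (CDKs), among them CDK9, the kinase of the elongation factor P-TEFb. The doses are those of the series design, and the treatment field of the labels gives the same figures in mM. Each of the 4 groups had 2 libraries, 8 in all, and the ± values below are SDs over the 2 libraries. The question of the series is how blocking OGT changes the need of prostate cancer cells for CDK9.

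The reads assigned to genes numbered 154367238 and 100148281 in control replicates 1 and 2 and 88244103 and 104520670 with OSMI-2. They numbered 92890671 and 111848023 with AT7519 and 105995544 and 60152710 with the combination. A level below 3 reads, 1.76 to 5.47 normalised counts depending on the library, was taken as the floor, and intervals and floors cover counting error only. Across the 19393 tested genes, which are not independent replicates, the log2 values of the 2 replicates correlated with Pearson r = 0.9938 in control, 0.9929 with OSMI-2, 0.9884 with AT7519 and 0.9881 with the combination. The first principal component held 66.2% of the variance and parted the 4 libraries with AT7519 from the 4 without it. The p-values below measure only the spread between these libraries, which may be technical, since nothing in the labels says that replicates were separate cultures.

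The 13 mitochondrially encoded mRNAs took 4.45% to 5.53% of counts in the libraries without AT7519 and 6.57% to 7.73% in those with it, and the 10 most abundant genes took 7.09% to 8.27% and 9.61% to 11.3%. Levels are therefore relative to a chosen scale, here that of the deposited values, on which the median gene changed by between -0.0176 and 0.0356 (log2) in every comparison. Scaled to equal mitochondrial mRNAs, the median gene changed by -0.105 with OSMI-2, -0.897 with AT7519 and -0.923 with the combination against control, and by -0.824 in the combination against OSMI-2. Scaled to equal totals it changed by -0.343 with AT7519, -0.234 with the combination, and -0.295 in the combination against OSMI-2. With equal upper quartiles it changed by 0.157 and 0.113 in those last 2 comparisons. Changes below are relative to the median gene on the deposited scale, and the text says where a direction turns on another scale.

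The comparison of OSMI-2 with control asks what blocking OGT alone did within 4 hours. At a preset correlation between genes, camera called falls of lists for DNA replication, ribosome biogenesis, heat shock and mitosis, and rises of those for cholesterol synthesis, amino acid stress and endoplasmic reticulum chaperones. None of the 7 passed with an estimated correlation (adjusted p of at least 0.265). The 2 genes of O-GlcNAc cycling moved apart. OGT rose 1.29-fold, from 23919 ± 580.5 to 30875 ± 1022 (log2 change 0.37, SE 0.091, adjusted p = 0.0434). MGEA5, the older symbol of the gene for the enzyme that removes O-GlcNAc, fell 1.31-fold, from 26614 ± 2544 to 20249 ± 959 (log2 change -0.39, SE 0.080, adjusted p = 0.0221). Among genes picked for large rises, the collagen gene COL16A1 rose 3.07-fold, from 421 ± 4.56 to 1307 ± 276 (log2 change 1.62, SE 0.20, adjusted p = 0.00456). Others picked were S100P (2.7-fold higher), NDUFA4L2 (2.29-fold), KIAA1683 (2.29-fold) and DMGDH (2.27-fold). Among genes with fewer reads, SPINK8 rose from 21.2 ± 5.01 to 70.5 ± 7.14 and PRSS1 from 70.7 ± 36.5 to 171 ± 41.2. Large falls were those of the arginase gene ARG1 (2.53-fold), CCDC83 (2.21-fold), PREX2 (2.08-fold), the testis bromodomain gene BRDT (2.05-fold), DHRS2 (1.99-fold) and the glucuronosyltransferase gene UGT2B10 (1.92-fold). Adjusted p was at most 0.0403 for all of these genes that are given without their own.

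Genes of the CDK9 axis, and KLK3, did not pass with OSMI-2. The log2 changes were 0.005 for CDK9, 0.087 for HEXIM1, -0.087 for MYC, -0.21 for MCL1, -0.25 for CCND1, 0.25 for KLK3 (prostate-specific antigen) and -0.091 for CDKN1A, with adjusted p of at least 0.175. In all, limma with Benjamini-Hochberg adjustment called 586 of 19393 genes, 125 higher and 461 lower. Of these, 27 changed by at least 1 on the log2 scale, and 3450 genes had an unadjusted p below 0.05. On recovered reads edgeR called 667 and DESeq2 1509. The balance of directions depended on the scale, with 144 higher and 118 lower at equal totals, 131 and 154 at equal upper quartiles, and 241 and 279 after quantile normalisation. The count rested on single libraries, as it was 297 without control replicate 1, 2 without control replicate 2, 117 without OSMI-2 replicate 1, 15 without OSMI-2 replicate 2, 892 without AT7519 replicate 1 and 883 without AT7519 replicate 2. Of the 34 called genes named for this comparison, 0 were called by limma without each of the 8 libraries in turn (1 was kept without control replicate 2 and 5 without OSMI-2 replicate 2), and limma without its variance trend called 0 genes, with 2788 at an unadjusted p below 0.05.

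Gene lists fixed before the data were examined showed the same changes by function. In fry only ribosome biogenesis genes passed (adjusted p = 0.0341), and the other 6 of the 7 lists of this paragraph had adjusted p from 0.0508 to 0.37. The camera runs without 1 library kept the preset correlation of 0.01, so they do not test the lists against correlation between genes. In these runs camera called the 7 lists without each of the 8 libraries in turn. Single genes were not, since of the 34 named, 22 were kept without control replicate 1, 1 without control replicate 2, 14 without OSMI-2 replicate 1 and 5 without OSMI-2 replicate 2. Where only 1 direction is given for a list, no member passed in the other. Of G1/S and DNA replication genes, 14 of 34 fell (31 adjusted over the list alone), camera adjusted p = 2.82e-22 (adjusted p = 0.278 with an estimated correlation). CDC25A fell 1.54-fold and MCM7 1.51-fold. Among ribosome biogenesis genes 17 of 30 fell (25 adjusted over the list alone), camera adjusted p = 2.06e-19 (adjusted p = 0.265 with an estimated correlation). LYAR fell 1.54-fold and NCL, the gene of nucleolin, 1.45-fold. In the heat shock list 9 of 21 fell (13 adjusted over the list alone), camera adjusted p = 9.56e-12 (adjusted p = 0.265 with an estimated correlation). HSPH1 fell 1.54-fold and HSP90AA1 1.52-fold. Of G2 and M phase genes 7 of 29 fell (17 adjusted over the list alone), camera adjusted p = 4.99e-10 (adjusted p = 0.3 with an estimated correlation). CDK1 was 1.46-fold, AURKA 1.4-fold and CCNB1 1.33-fold lower. Cholesterol synthesis and SREBP2 target genes went the other way, as 8 of 25 rose and 2 fell (15 and 4 adjusted over the list alone), camera adjusted p = 2.3e-09 (adjusted p = 0.272 with an estimated correlation). MVD rose 1.99-fold and INSIG1 1.88-fold. Of ATF4 and integrated stress response genes 3 of 32 rose (6 adjusted over the list alone), camera adjusted p = 2.65e-09 (adjusted p = 0.398 with an estimated correlation). SLC7A11 was 1.55-fold and PCK2 1.41-fold higher. Of the list of endoplasmic reticulum chaperones 2 of 22 rose (6 adjusted over the list alone), camera adjusted p = 1.98e-06 (adjusted p = 0.317 with an estimated correlation). That list also holds genes that are not chaperones, such as SEC24D. DNAJB9 was 2.02-fold and SEC24D 1.6-fold higher. For the genes named in these lists, adjusted p was at most 0.0287.

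With OSMI-2 camera also called falls of ribosomal proteins, oxidative phosphorylation genes, splicing factors, DNA repair genes, CDKs and cyclins and elongation factors, with adjusted p of at most 0.0131 (adjusted p of at least 0.265 with an estimated correlation). Members that rose and fell, with counts adjusted over the list alone in parentheses, were 0 and 3 of 78 cytosolic ribosomal proteins (0 and 20), 0 and 6 of 35 nuclear oxidative phosphorylation genes (0 and 18), 0 and 8 of 39 splicing factors (0 and 16), 0 and 3 of 37 DNA repair genes (1 and 8), 0 and 2 of 25 CDKs and cyclins (1 and 11) and 0 and 1 of 34 elongation factors (0 and 1). Of luminal prostate markers, 2 of 19 rose (2 adjusted over the list alone), camera adjusted p = 0.0421 (adjusted p = 0.518 with an estimated correlation), and SLC45A3 was 1.38-fold higher (adjusted p = 0.018). For the mitochondrial mRNAs, 0 of 13 passed in either direction, adjusted over the list alone or over all genes, camera adjusted p = 0.00575 (adjusted p = 0.566 with an estimated correlation). Of zinc finger genes, 1 of 477 rose (0 adjusted over the list alone), camera adjusted p = 0.0417 (adjusted p = 0.392 with an estimated correlation), and their median turned from 0.036 to -0.052 when scaled to mitochondrial mRNAs. The p53 targets as a list did not pass, where 2 of 29 rose and 2 fell (2 and 4 adjusted over the list alone), camera adjusted p = 0.279 (adjusted p = 0.672 with an estimated correlation). Within it GDF15 rose 1.48-fold (adjusted p = 0.0277) and BBC3 1.66-fold (adjusted p = 0.023). Nor did the BCL2 family and inhibitors of apoptosis, where 1 of 20 rose and 1 fell (2 and 1 adjusted over the list alone), camera adjusted p = 0.915 (adjusted p = 0.957 with an estimated correlation), whose median and mean differed in sign and in which BIRC5 fell 1.36-fold (adjusted p = 0.0137). The remaining lists reported gave camera adjusted p from 0.125 to 0.915, and adjusted p of at least 0.605 with an estimated correlation.

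Single libraries decided several of these further calls with OSMI-2. Without control replicate 1, adjusted p was 0.266 for zinc finger genes and 0.294 for luminal markers. It was 0.0623 for elongation factors without control replicate 2 and 0.0627 for zinc finger genes without OSMI-2 replicate 1. Without OSMI-2 replicate 2 it was 0.0542 for zinc finger genes, 0.283 for luminal markers, 0.664 for mitochondrial mRNAs and 0.116 for elongation factors. Luminal markers had 0.0567 and 0.0562 without AT7519 replicates 1 and 2. Without OSMI-2 replicate 1 the lists of p53 targets (0.0297), NRF2 targets (0.0103), fatty acid synthesis genes (0.000427) and histones (0.00172) passed, and without control replicate 2 histones did (0.00145).

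The comparison of AT7519 with control asks what CDK inhibition alone did. At 4 hours limma called 10323 genes with AT7519. Among them were MEPCE, HEXIM1 and HEXIM2, whose proteins hold P-TEFb inactive. MEPCE fell 10.1-fold, from 10688 ± 80.5 to 1071 ± 214 (log2 change -3.33, SE 0.12, adjusted p = 9.69e-10). HEXIM1 fell 3.11-fold, from 6489.8 ± 324 to 2084 ± 57.5 (log2 change -1.64, SE 0.11, adjusted p = 7.09e-08), and HEXIM2 fell 4.24-fold. Cyclin D1 mRNA (CCND1) fell 2.02-fold, while cyclin L1 (CCNL1), a splicing cyclin, rose 4.92-fold (adjusted p of at most 1.31e-06 for HEXIM2, CCND1 and CCNL1). CDK9 itself rose 1.7-fold (adjusted p = 7.62e-06), but did not pass when scaled to mitochondrial mRNAs (log2 change -0.13, adjusted p = 0.368). MCL1, an anti-apoptotic gene, rose 1.38-fold (adjusted p = 0.000201) and CDKN1A rose 1.23-fold (adjusted p = 0.00899), and both turned to falls on that scale, while CDKN1A did not pass at equal totals (adjusted p = 0.719). CDKN1A did not pass without control replicate 1 (adjusted p = 0.124) or without AT7519 replicate 2 (adjusted p = 0.0827). OGT (log2 change 0.13), MGEA5 (-0.14), MYC (0.13) and KLK3 (0.11) did not pass, with adjusted p of at least 0.151. Scaled to mitochondrial mRNAs, OGT, MYC and KLK3 fell (log2 change -0.77, -0.77 and -0.79, adjusted p of at most 4.2e-09). OGT (adjusted p = 0.0355) and KLK3 (adjusted p = 0.000677) also fell after quantile normalisation, and MYC at equal totals (adjusted p = 0.0287). On the deposited scale MGEA5 passed without control replicate 2 (adjusted p = 0.049) and OGT without AT7519 replicate 1 (adjusted p = 0.0111).

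Among genes picked for the largest changes with AT7519, CCDC87 went from 183 ± 4.2 to 2.28 ± 0.355, TIGD3 from 144 ± 47.9 to 4.06 ± 1.43, FAM46A from 109 ± 31.9 to 4.32 ± 2.52, FUT4 from 190.2 ± 30.2 to 8.12 ± 2.86 and the Wnt receptor gene FZD8 from 439 ± 18.8 to 17.8 ± 3.56. With AT7519 these levels were near the floor in all but FZD8. Rises came from low control levels, as for the small nucleolar RNAs SNORD59A (from 11.2 ± 0.933 to 403 ± 80.2) and SNORD37 (from 17.2 ± 11.4 to 283 ± 97.2), which lie within ATP5F1B and EEF2. LRRC70 (from 7.46 ± 8.88 to 136 ± 4.36) and RPA4 (from 8.17 ± 6.57 to 163 ± 60.8), within IPO11 and DIAPH2, also rose. Adjusted p was at most 3.61e-05 for these 9 genes. In all, limma called 10323 of 19393 genes, 5045 higher and 5278 lower. Large changes were mostly falls, with 710 genes higher and 2348 lower by at least 1 on the log2 scale. The balance followed the scale, with 2036 higher and 8364 lower at equal totals and 383 and 14496 when scaled to mitochondrial mRNAs. On recovered reads edgeR called 10420.

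**Figure D1:**
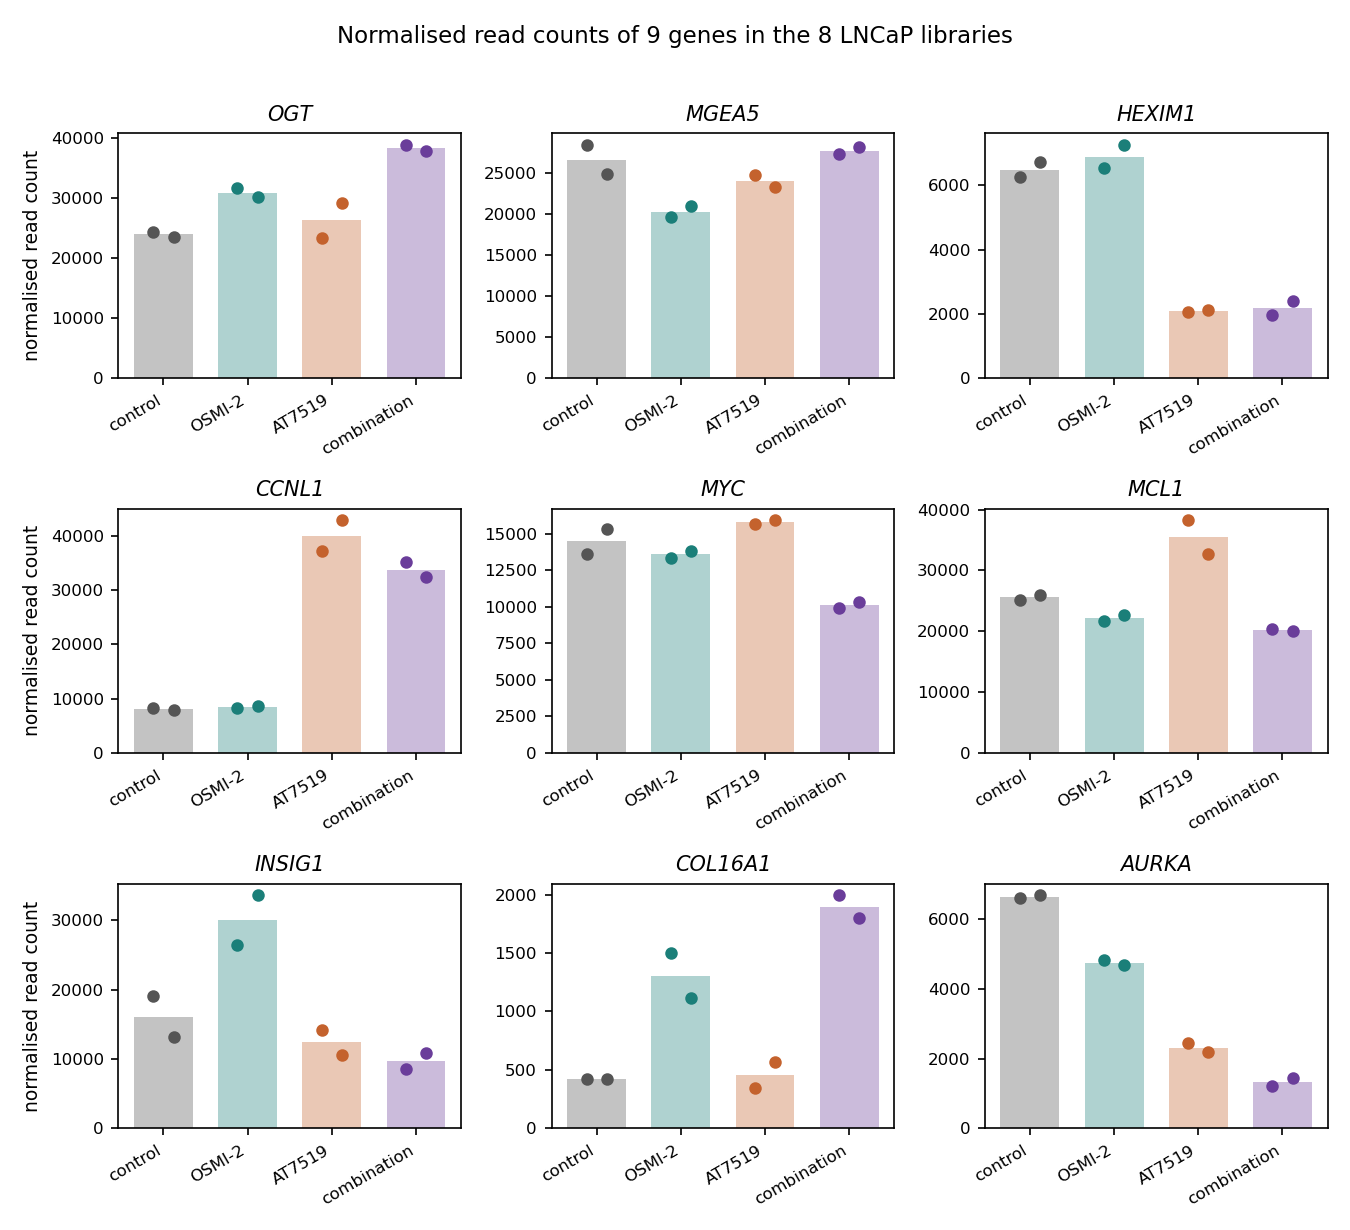
Normalised read counts (y axis) of 9 genes in the 4 treatment groups (x axis), on the deposited scale, where bars are group means and dots the 2 libraries. INSIG1 was 16104 in control, 29979.6 with OSMI-2 and 9720.0 with both agents on the scale as deposited.

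By function, AT7519 lowered immediate early genes, zinc finger genes and DNA repair genes relative to the median gene, and raised ribosomal protein and respiratory chain genes. Of immediate early genes, 4 of 29 rose and 19 fell (4 and 21 adjusted over the list alone), camera adjusted p = 0.00254 (adjusted p = 0.197 with an estimated correlation). GADD45B fell 7.54-fold and DUSP6 went from 36.4 ± 1.6 to 2.28 ± 0.355, while JUND rose 1.89-fold and DUSP1 1.43-fold, the last a fall when scaled to mitochondrial mRNAs. Of zinc finger genes, 69 of 477 rose and 262 fell (71 and 269 adjusted over the list alone), camera adjusted p = 2.65e-08 (adjusted p = 0.111 with an estimated correlation). Of DNA repair genes, 6 of 37 rose and 20 fell (6 and 20 adjusted over the list alone), camera adjusted p = 0.00741 (adjusted p = 0.739 with an estimated correlation). ERCC4 was 4.13-fold and ERCC6 2.87-fold lower. Of the BCL2 family and inhibitors of apoptosis, 5 of 20 rose and 12 fell (5 and 12 adjusted over the list alone), camera adjusted p = 0.0357 (adjusted p = 0.739 with an estimated correlation). BCL2L11 fell 4.18-fold. These 4 falls kept their direction under the 4 other scalings. Of cytosolic ribosomal proteins, 78 of 78 rose (78 adjusted over the list alone), camera adjusted p = 1.35e-35 (adjusted p = 0.0922 with an estimated correlation). They rose on the deposited scale, but their median went from 0.83 to -0.076 when scaled to mitochondrial mRNAs. The nuclear oxidative phosphorylation genes went with them, as 35 of 35 rose (35 adjusted over the list alone), camera adjusted p = 1.05e-17 (adjusted p = 0.0922 with an estimated correlation). Their medians were 0.72 and -0.18 on those 2 scales. RPS10 rose 3.36-fold, RPS15A 2.76-fold, NDUFV2 5.49-fold and NDUFA9 2.44-fold. Of the mitochondrial mRNAs, 13 of 13 rose (13 adjusted over the list alone), camera adjusted p = 2.23e-09 (adjusted p = 0.407 with an estimated correlation). Of splicing factors, 28 of 39 rose and 3 fell (29 and 3 adjusted over the list alone), camera adjusted p = 4.47e-07 (adjusted p = 0.242 with an estimated correlation). CLK1 and CLK3 were each 2.43-fold higher and LUC7L3 1.6-fold lower. The median of splicing factors, 0.41, became -0.49 when scaled to mitochondrial mRNAs. Genes named in these lists had adjusted p of at most 0.00161.

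Camera called rises with AT7519 of endoplasmic reticulum chaperones, heat shock genes and NRF2 targets. In the first 15 of 22 rose and 4 fell (15 and 4 adjusted over the list alone), camera adjusted p = 0.00254 (adjusted p = 0.739 with an estimated correlation), in the next 12 of 21 rose and 3 fell (12 and 3 adjusted over the list alone), camera adjusted p = 0.03 (adjusted p = 0.739 with an estimated correlation), and in the last 13 of 23 rose and 5 fell (13 and 5 adjusted over the list alone), camera adjusted p = 0.0298 (adjusted p = 0.739 with an estimated correlation). The medians of 0.60, 0.38 and 0.41 turned to -0.30, -0.52 and -0.48 when scaled to mitochondrial mRNAs, heat shock genes also after quantile normalisation (-0.00877). Other lists held members moving both ways, with rises and falls (adjusted over the list alone in parentheses) of 11 and 14 of 34 elongation factors (11 and 14), 13 and 8 of 25 CDKs and cyclins (13 and 8), 12 and 11 of 29 p53 targets (12 and 12) and 7 and 12 of 32 ATF4 targets (8 and 12). Within these, CDK13 fell 2.68-fold and CCNE2 2.7-fold. GDF15 rose 2.03-fold, AEN 1.92-fold, NELFCD 1.64-fold and, of luminal markers, KRT8 1.53-fold, and scaled to mitochondrial mRNAs KRT8 fell and NELFCD did not pass (adjusted p = 0.154). Adjusted p was at most 1.47e-05 for these genes on the deposited scale. These 4 lists and the remaining ones gave camera adjusted p from 0.0967 to 0.989, and adjusted p of at least 0.739 with an estimated correlation. Median and mean differed in sign for G1/S genes, p53 targets, interferon-stimulated genes and luminal markers.

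The comparison of the combination with control asks what both agents did together. The combination lowered MYC and MCL1, which neither agent alone lowered past the threshold on the deposited scale. With AT7519 alone both fell when scaled to mitochondrial mRNAs, and MYC at equal totals. MYC fell 1.43-fold, from 14484 ± 1181 to 10140.1 ± 301 (log2 change -0.51, SE 0.078, adjusted p = 7.14e-05). MCL1 fell 1.26-fold, from 25586 ± 548 to 20236 ± 194 (log2 change -0.34, SE 0.080, adjusted p = 0.00245). Among genes with large falls, IER5 fell 27.5-fold, SGK1 16.5-fold, PLK2 7.47-fold, BTG2 6.14-fold and the mitotic kinase gene AURKA 5.02-fold. OGT rose 1.6-fold (adjusted p = 2e-05), KLK3 1.42-fold (adjusted p = 0.00175) and KLK2 1.75-fold (adjusted p = 0.000133), although scaled to mitochondrial mRNAs OGT and KLK3 fell and KLK2 did not pass (adjusted p = 0.256), nor did KLK3 after quantile normalisation (adjusted p = 0.511). MEPCE was 10.1-fold and HEXIM1 2.99-fold below control, and CCND1 was 1.69-fold below it. Other large falls left low levels, as FZD8 went from 439 ± 18.8 to 5.01 ± 4.51, SOX9 from 225 ± 41.5 to 6.95 ± 4.67 and FRAT1 from 742 ± 43.3 to 30.2 ± 29.8. EID3, which lies within TXNRD1, rose from 27 ± 5.8 to 613 ± 124, SNORD37 from 17.2 ± 11.4 to 459 ± 39.1 and LRRC70 from 7.46 ± 8.88 to 125 ± 21.9. Adjusted p was at most 4.22e-05 for the genes given here without their own.

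CDK9 rose 1.25-fold with the combination (adjusted p = 0.00854), which became a fall when scaled to mitochondrial mRNAs, and CDKN1A fell 1.22-fold (adjusted p = 0.0126). CDK9 did not pass without combination replicate 1 (adjusted p = 0.113), nor CDKN1A without control replicate 2 (adjusted p = 0.161) or combination replicate 2 (adjusted p = 0.0711). MGEA5 (log2 change 0.062) did not pass, but it fell at equal totals (-0.20, adjusted p = 0.0493), after quantile normalisation (-0.20, adjusted p = 0.0472) and when scaled to mitochondrial mRNAs (-0.89, adjusted p = 1.65e-12). In all, limma called 10448 genes, 5097 higher and 5351 lower, with 1049 higher and 2456 lower by at least 1 on the log2 scale, and edgeR called 10541. The split was 2652 higher and 7369 lower at equal totals, 6476 and 4485 at equal upper quartiles, and 432 and 14384 when scaled to mitochondrial mRNAs.

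With the combination camera called falls of 7 lists. Of immediate early genes, 3 of 29 rose and 22 fell (3 and 22 adjusted over the list alone), camera adjusted p = 8.21e-06 (adjusted p = 0.0838 with an estimated correlation). Against that trend JUND rose 2.27-fold and KLF10 1.45-fold, the latter a fall when scaled to mitochondrial mRNAs. Of G2 and M phase genes, 1 of 29 rose and 18 fell (1 and 18 adjusted over the list alone), camera adjusted p = 0.000265 (adjusted p = 0.509 with an estimated correlation). Of G1/S and DNA replication genes, 20 of 34 fell (1 higher and 21 lower adjusted over the list alone), camera adjusted p = 0.000201 (adjusted p = 0.678 with an estimated correlation). CCNE2 was 4.25-fold lower. Of the BCL2 family and inhibitors of apoptosis, 2 of 20 rose and 12 fell (3 and 12 adjusted over the list alone), camera adjusted p = 0.002 (adjusted p = 0.509 with an estimated correlation). BIRC3 was 4.93-fold and PMAIP1 4.67-fold lower. Of DNA repair genes, 5 of 37 rose and 22 fell (5 and 22 adjusted over the list alone), camera adjusted p = 0.000458 (adjusted p = 0.509 with an estimated correlation). Among elongation factors 7 of 34 rose and 18 fell (7 and 18 adjusted over the list alone), camera adjusted p = 0.00279 (adjusted p = 0.509 with an estimated correlation). Among zinc finger genes 53 of 477 rose and 288 fell (55 and 294 adjusted over the list alone), camera adjusted p = 1.04e-10 (adjusted p = 0.0838 with an estimated correlation). Ribosomal protein, oxidative phosphorylation, splicing and chaperone genes rose on the deposited scale. In the first of these lists 78 of 78 rose (78 adjusted over the list alone), camera adjusted p = 1.47e-32 (adjusted p = 0.0838 with an estimated correlation), and in the next 32 of 35 rose (32 adjusted over the list alone), camera adjusted p = 3.86e-12 (adjusted p = 0.0905 with an estimated correlation). Then came splicing, where 25 of 39 rose and 5 fell (25 and 5 adjusted over the list alone), camera adjusted p = 0.000246 (adjusted p = 0.44 with an estimated correlation), and chaperones, where 15 of 22 rose and 2 fell (15 and 2 adjusted over the list alone), camera adjusted p = 0.00223 (adjusted p = 0.509 with an estimated correlation). The 4 medians of 0.77, 0.53, 0.28 and 0.46 turned to -0.19, -0.42, -0.68 and -0.50 when scaled to mitochondrial mRNAs. RPS10 was 3.21-fold and NDUFV2 5.35-fold higher. Of the mitochondrial mRNAs, 13 of 13 rose (13 adjusted over the list alone), camera adjusted p = 1.36e-09 (adjusted p = 0.44 with an estimated correlation). Genes named for these lists had adjusted p of at most 0.00269.

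Several stress and lipid lists split with the combination. Within p53 targets, 6 of 29 rose and 15 fell (7 and 15 adjusted over the list alone), camera adjusted p = 0.0537 (adjusted p = 0.509 with an estimated correlation). GDF15 rose 1.64-fold but did not pass when scaled to mitochondrial mRNAs (adjusted p = 0.0641). Of ATF4 targets, 14 of 32 rose and 9 fell (14 and 9 adjusted over the list alone), camera adjusted p = 0.506 (adjusted p = 0.932 with an estimated correlation). PCK2 rose 2.01-fold and PHGDH 1.89-fold (not passed when scaled to mitochondrial mRNAs, adjusted p = 0.77), and CHAC1 fell 8.46-fold. The median of 0.21 and the mean of -0.14 of the list differed in sign. Cholesterol genes did not pass as a list, where 6 of 25 rose and 10 fell (7 and 11 adjusted over the list alone), camera adjusted p = 0.372 (adjusted p = 0.891 with an estimated correlation). INSIG1 was 1.64-fold lower, which did not pass without control replicate 1 (adjusted p = 0.063). Of heat shock genes, 7 of 21 rose and 5 fell (7 and 5 adjusted over the list alone), camera adjusted p = 0.728 (adjusted p = 0.932 with an estimated correlation), with DNAJB1 5.82-fold lower. For these genes adjusted p was at most 0.00289. The remaining lists gave camera adjusted p from 0.0906 to 0.927, and adjusted p of at least 0.509 with an estimated correlation. Median and mean also differed in sign for NRF2 targets, fatty acid synthesis genes, interferon-stimulated genes, histones and luminal markers.

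The comparison of the combination with AT7519 asks what blocking OGT added in cells whose CDKs were inhibited. Added to AT7519, OSMI-2 lowered MCL1, MYC, CDKN1A and the P-TEFb genes CDK9 and CCNT1. MCL1 fell 1.75-fold, from 35509 ± 3882 to 20236 ± 194 (log2 change -0.81, SE 0.080, adjusted p = 6.29e-05). MYC fell 1.56-fold, from 15802 ± 199 to 10140.1 ± 301 (log2 change -0.64, SE 0.078, adjusted p = 0.000177). CDKN1A fell 1.5-fold (adjusted p = 0.000532), CDK9 1.37-fold (adjusted p = 0.00356) and CCNT1 1.82-fold (adjusted p = 0.000344). OGT rose 1.47-fold (adjusted p = 0.000998), KLK2 1.6-fold (adjusted p = 0.00311) and KLK3 1.31-fold (adjusted p = 0.0273). MGEA5 (log2 change 0.21), HEXIM1 (0.057) and CCND1 (0.26) did not pass, except CCND1 without combination replicate 1 (adjusted p = 0.0173). Without combination replicate 2 the adjusted p was 0.0525 for CDK9, 0.312 for KLK3 and 0.0516 for KLK2. For KLK3 it was 0.0935 without AT7519 replicate 1 and 0.0689 without AT7519 replicate 2.

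The largest falls picked here were those of IER5 (6.65-fold), CYR61 (5.63-fold), CITED2 (4.7-fold), the microRNA host gene MIR17HG (4.68-fold) and SOX9, which went from 53.3 ± 25.1 to 6.95 ± 4.67. Rises were those of COL16A1 (4.28-fold), CAPN3 (3.67-fold), PDE2A (3.6-fold) and S100P (3.5-fold), and COL16A1 and S100P also rose with OSMI-2 alone. Adjusted p was at most 0.00226 for these 9 genes. In all, limma called 3815 genes, 1399 higher and 2416 lower, with 347 higher and 224 lower by at least 1 on the log2 scale, and edgeR called 3489. The split was 2023 higher and 1534 lower at equal totals, 2191 and 1440 at equal upper quartiles, and 1374 and 1455 after quantile normalisation. The count was 2191 without AT7519 replicate 1 and 1683 without combination replicate 2.

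By function, camera at the preset correlation called falls of 9 lists and a rise of ATF4 targets when OSMI-2 was added to AT7519. The medians of the lists called here kept their direction under the 4 other scalings. In fry G1/S genes (adjusted p = 0.055) and ATF4 targets (adjusted p = 0.233) did not pass, while the other lists of this paragraph that camera called did. Scaled to mitochondrial mRNAs no list passed in fry, the lowest adjusted p being 0.0708 for immediate early genes. Of G1/S and DNA replication genes, 20 of 34 fell (25 adjusted over the list alone), camera adjusted p = 1.1e-10 (adjusted p = 0.477 with an estimated correlation). CDC25A was 2.22-fold and GINS3 1.65-fold lower. Of ribosome biogenesis genes, 21 of 30 fell (23 adjusted over the list alone), camera adjusted p = 1.1e-10 (adjusted p = 0.351 with an estimated correlation). RRS1 was 1.94-fold and WDR43 1.83-fold lower. Of heat shock genes, 15 of 21 fell (16 adjusted over the list alone), camera adjusted p = 8.87e-09 (adjusted p = 0.299 with an estimated correlation). DNAJB1 was 1.91-fold and HSF2 1.79-fold lower. Of G2 and M phase genes, 17 of 29 fell (1 higher and 18 lower adjusted over the list alone), camera adjusted p = 3.7e-08 (adjusted p = 0.382 with an estimated correlation). AURKA was 1.74-fold and PLK1 1.71-fold lower. Of cholesterol genes, 10 of 25 fell (14 adjusted over the list alone), camera adjusted p = 2.99e-06 (adjusted p = 0.382 with an estimated correlation). EBP was 1.7-fold lower. Of p53 targets, 1 of 29 rose and 14 fell (1 and 17 adjusted over the list alone), camera adjusted p = 2.99e-06 (adjusted p = 0.299 with an estimated correlation). PLK2 was 3.98-fold and BTG2 3.93-fold lower. PMAIP1, of the BCL2 family and inhibitors of apoptosis, a list not called here (camera adjusted p = 0.116), was 1.96-fold lower. Elongation factors fell, where 1 of 34 rose and 15 fell (1 and 17 adjusted over the list alone), camera adjusted p = 2.12e-05 (adjusted p = 0.321 with an estimated correlation), with ELL 1.91-fold lower. So did CDKs and cyclins, where 13 of 25 fell (2 higher and 17 lower adjusted over the list alone), camera adjusted p = 4.49e-06 (adjusted p = 0.299 with an estimated correlation), with CDK8 1.72-fold lower. Of immediate early genes, 1 of 29 rose and 11 fell (1 and 12 adjusted over the list alone), camera adjusted p = 0.000386 (adjusted p = 0.299 with an estimated correlation). FOSB rose 2.81-fold, which did not pass without combination replicate 2 (adjusted p = 0.0502). Of ATF4 targets, 8 of 32 rose (12 adjusted over the list alone), camera adjusted p = 2.99e-06 (adjusted p = 0.568 with an estimated correlation). SLC7A11 was 1.65-fold and ALDH1L2 1.66-fold higher. ALDH1L2 did not pass without any 1 of 6 libraries. Its adjusted p was 0.0512 without control replicate 1, 0.0522 and 0.051 without OSMI-2 replicates 1 and 2, 0.0622 and 0.105 without AT7519 replicates 1 and 2, and 0.18 without combination replicate 2. The genes named in this paragraph had adjusted p of at most 0.033 with all libraries.

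In the combination against AT7519, falls were called for 3 more lists. Of nuclear oxidative phosphorylation genes, 14 of 35 fell (16 adjusted over the list alone), camera adjusted p = 2.99e-06 (adjusted p = 0.299 with an estimated correlation). Of splicing factors, 8 of 39 fell (10 adjusted over the list alone), camera adjusted p = 0.00878 (adjusted p = 0.477 with an estimated correlation). Of fatty acid synthesis genes, 1 of 16 rose and 7 fell (1 and 7 adjusted over the list alone), camera adjusted p = 0.0179 (adjusted p = 0.601 with an estimated correlation). In fry splicing factors (adjusted p = 0.055) and fatty acid synthesis genes (adjusted p = 0.185) did not pass. The remaining lists gave camera adjusted p from 0.0589 to 0.912, and adjusted p of at least 0.477 with an estimated correlation, and median and mean differed in sign for histones. BIRC3, of the BCL2 family and inhibitors of apoptosis, fell 1.86-fold (adjusted p = 0.00849), which did not pass without combination replicate 1 (adjusted p = 0.0691).

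**Figure D2:**
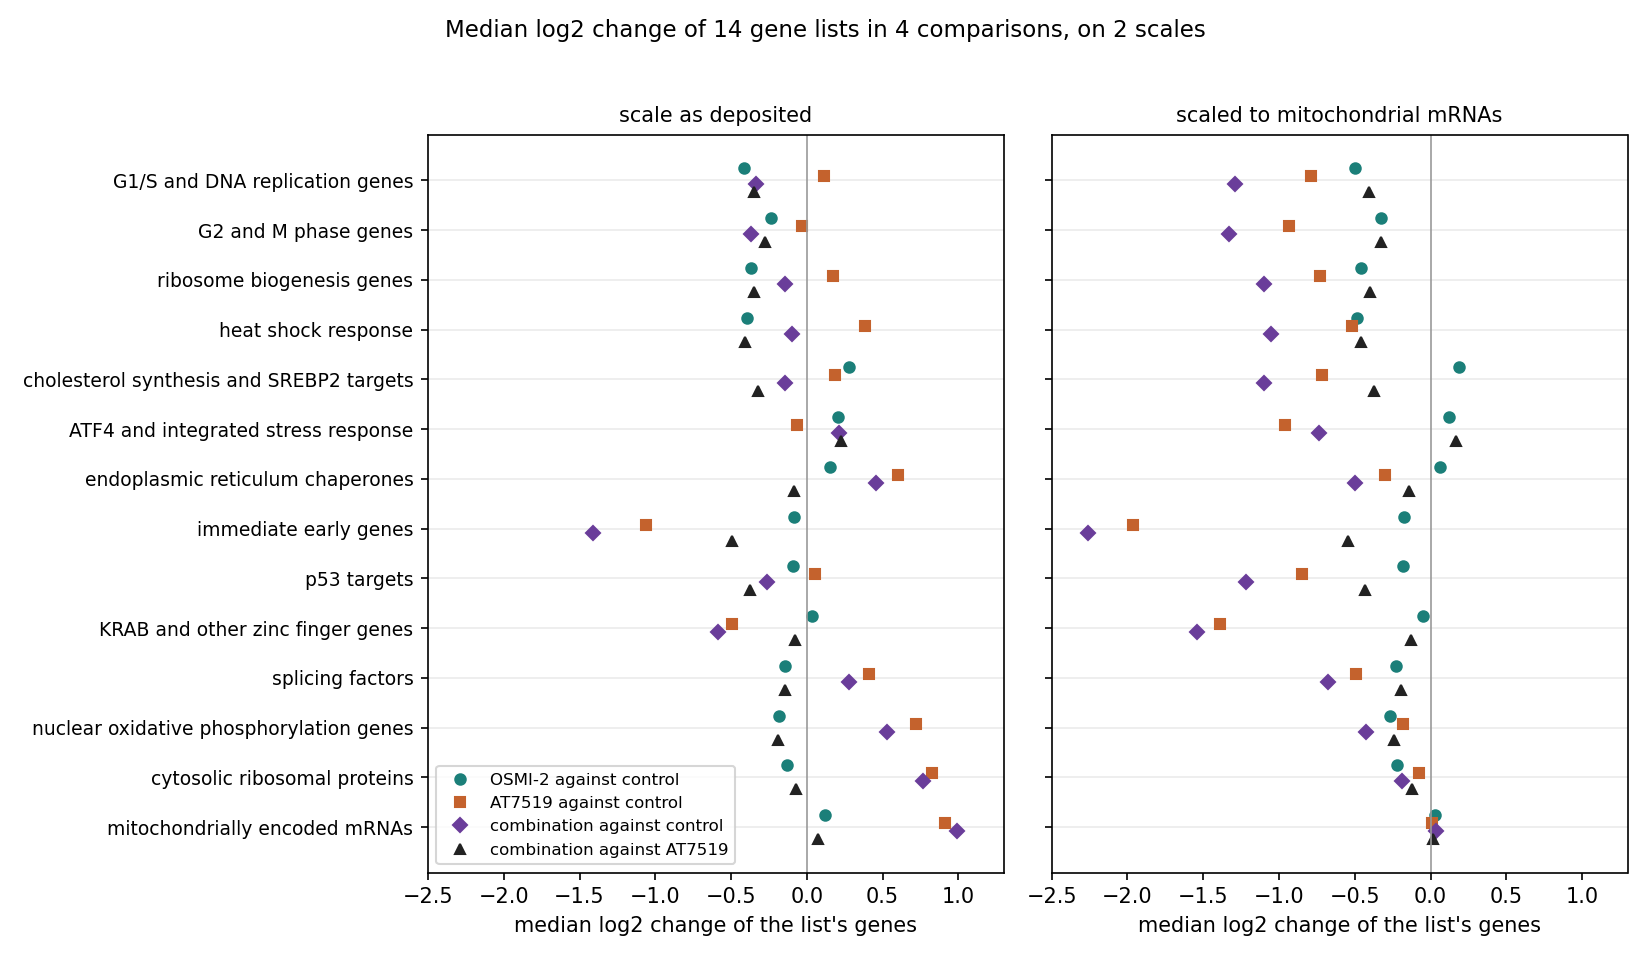
Median log2 change (x axis) of 14 gene lists (y axis) in 4 comparisons, on the deposited scale at left and scaled to equal mitochondrial mRNAs at right. With AT7519 the ribosomal protein median was 0.83 at left and -0.076 at right, while the immediate early median was -1.06 and -1.96.

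The comparison of the combination with OSMI-2 asks what CDK inhibition added in cells whose OGT was blocked. AT7519 on top of OSMI-2 lowered HEXIM1 3.18-fold. Camera called a fall of immediate early genes and a rise of ribosomal protein genes, as with AT7519 alone. It lowered MYC 1.34-fold and CCND1 1.42-fold, and took the cholesterol gene INSIG1 down 3.08-fold. Of immediate early genes, 3 of 29 rose and 22 fell (3 and 23 adjusted over the list alone), camera adjusted p = 5.1e-06 (adjusted p = 0.0603 with an estimated correlation). Of cholesterol genes, 3 of 25 rose and 15 fell (3 and 15 adjusted over the list alone), camera adjusted p = 0.0107 (adjusted p = 0.595 with an estimated correlation). Of cytosolic ribosomal proteins, 78 of 78 rose (78 adjusted over the list alone), camera adjusted p = 4.31e-35 (adjusted p = 0.0603 with an estimated correlation). Their median of 0.89 became 0.023 when scaled to mitochondrial mRNAs, where fry did not pass (adjusted p = 0.652). CDK1 rose 1.58-fold and BIRC5 1.48-fold, and scaled to mitochondrial mRNAs BIRC5 fell and CDK1 did not pass (adjusted p = 0.122). CHAC1 fell 6.97-fold. FZD8 went from 453 ± 25.4 to 5.01 ± 4.51, FRAT1 from 854 ± 13 to 30.2 ± 29.8, OTUD1 from 528 ± 86.5 to 23.9 ± 28.6 and SOX9 from 174 ± 42.8 to 6.95 ± 4.67. In the other direction EID3 went from 13.1 ± 0.925 to 613 ± 124 and SNORD14A, within RPS13, from 36.6 ± 11.5 to 788 ± 20.1. These genes had adjusted p of at most 0.000487. In all, limma called 10630 genes, 5342 higher and 5288 lower, with 759 higher and 2463 lower by at least 1 on the log2 scale, and edgeR called 10665. The split was 2129 higher and 7862 lower at equal totals and 414 and 13674 when scaled to mitochondrial mRNAs.

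Other lists called in the combination against OSMI-2 fell or rose as they did with AT7519 alone, apart from elongation factors. Of zinc finger genes, 44 of 477 rose and 300 fell (46 and 300 adjusted over the list alone), camera adjusted p = 6.61e-13 (adjusted p = 0.0603 with an estimated correlation). Of the BCL2 family and inhibitors of apoptosis, 3 of 20 rose and 13 fell (3 and 13 adjusted over the list alone), camera adjusted p = 0.0019 (adjusted p = 0.505 with an estimated correlation). Among elongation factors 9 of 34 rose and 18 fell (9 and 18 adjusted over the list alone), camera adjusted p = 0.042 (adjusted p = 0.595 with an estimated correlation). In nuclear oxidative phosphorylation genes 35 of 35 rose (35 adjusted over the list alone), camera adjusted p = 2.68e-16 (adjusted p = 0.0603 with an estimated correlation), and in splicing factors 26 of 39 rose and 4 fell (29 and 4 adjusted over the list alone), camera adjusted p = 4.01e-07 (adjusted p = 0.239 with an estimated correlation). Of mitochondrial mRNAs, 13 of 13 rose (13 adjusted over the list alone), camera adjusted p = 1.16e-08 (adjusted p = 0.46 with an estimated correlation). The medians of oxidative phosphorylation genes and splicing factors, 0.73 and 0.44, turned to -0.14 and -0.42 when scaled to mitochondrial mRNAs. The remaining lists gave camera adjusted p from 0.0615 to 0.773, and adjusted p of at least 0.595 with an estimated correlation, and median and mean differed in sign for CDKs and cyclins, G1/S genes, interferon-stimulated genes and histones.

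The interaction asks whether OSMI-2 acted differently with AT7519 present than without it, as the log2 change in the combination against AT7519 minus that of OSMI-2 against control. INSIG1, a gene of the SREBP2 list, went from 16104 ± 4135 to 29979.6 ± 5096 when OSMI-2 was given alone, and from 12369.8 ± 2562 to 9720.0 ± 1682 when it was given with AT7519 (interaction -1.25, SE 0.24, adjusted p = 0.0274). Of the genes picked for size, CYR61 (-2.27), IER5 (-2.35), CITED2 (-2.15), BTG2 (-1.95), MIR17HG (-1.94), BTG1 (-1.68) and PLK2 (-1.54) also lay below the sum of both agents. So did MCL1 (-0.60, adjusted p = 0.0241), MYC (-0.55, adjusted p = 0.03), the P-TEFb cyclin CCNT1 (-0.80), BRD2 (-0.73), BBC3 (-1.17) and DNAJC3 (-0.61). MGEA5 (0.60, adjusted p = 0.0243), SMAD6 (1.41), PPP1R10 (1.29), ZNF382 (1.07) and XRCC2 (0.79) lay above it. For all 19 genes adjusted p was at most 0.0469.

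The interaction was not past the threshold for OGT (0.19), CDK9 (-0.46), HEXIM1 (-0.030), CCND1 (0.51), KLK3 (0.14) and CDKN1A (-0.49), except without combination replicate 1 for CDK9 (adjusted p = 0.0383) and CCND1 (adjusted p = 0.0199). In all, limma called 201 genes, 12 above the sum and 189 below it, of which 72 differed by at least 1 on the log2 scale. There were 1962 at an unadjusted p below 0.05, and edgeR called 184 and DESeq2 563. The count was 4 without control replicate 1, 2 without control replicate 2, 4 without OSMI-2 replicate 1, 7 without OSMI-2 replicate 2, 72 without AT7519 replicate 1, 490 without AT7519 replicate 2, 434 without combination replicate 1 and 55 without combination replicate 2. Of the 19 called genes named, 0 were called without each of the 8 libraries in turn, and limma without its variance trend called 0 genes, with 1800 at an unadjusted p below 0.05.

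The cholesterol list lay below the sum of the agents as a group, where a member below the sum is counted as a fall and one above it as a rise. Of its genes, 10 of 25 fell (19 adjusted over the list alone), camera adjusted p = 8.57e-27 (adjusted p = 0.163 with an estimated correlation), with a median of -0.55. By sign, 21 of its 25 genes were above control with OSMI-2 alone, 23 were below AT7519 in the combination, and 24 had an interaction below 0. Immediate early genes lay below it too, where 6 of 29 fell (1 higher and 9 lower adjusted over the list alone), camera adjusted p = 1.03e-06 (adjusted p = 0.163 with an estimated correlation). So did p53 targets, where 6 of 29 fell (10 adjusted over the list alone), camera adjusted p = 7.89e-08 (adjusted p = 0.23 with an estimated correlation) and endoplasmic reticulum chaperones, where 1 of 22 fell (4 adjusted over the list alone), camera adjusted p = 2.72e-08 (adjusted p = 0.402 with an estimated correlation). Camera at the preset correlation called these 4 lists without each of the 8 libraries in turn, which does not test them against correlation between genes. Of the 19 genes named, 0 were kept without control replicate 1, control replicate 2 or OSMI-2 replicate 1, and 1 without OSMI-2 replicate 2. Further lists were called below the sum. Of fatty acid synthesis genes, 1 of 16 fell (2 adjusted over the list alone), camera adjusted p = 2.56e-05 (adjusted p = 0.482 with an estimated correlation). Of zinc finger genes, 2 of 477 rose and 13 fell (3 and 43 adjusted over the list alone), camera adjusted p = 0.000117 (adjusted p = 0.247 with an estimated correlation). Among elongation factors 2 of 34 fell (4 adjusted over the list alone), camera adjusted p = 0.00243 (adjusted p = 0.482 with an estimated correlation). Among CDKs and cyclins 1 of 25 fell (1 higher and 2 lower adjusted over the list alone), camera adjusted p = 0.0178 (adjusted p = 0.482 with an estimated correlation). In the BCL2 family and inhibitors of apoptosis 2 of 20 fell (6 adjusted over the list alone), camera adjusted p = 0.0434 (adjusted p = 0.586 with an estimated correlation). Among NF-kB targets 0 of 12 fell (1 adjusted over the list alone), camera adjusted p = 0.0471 (adjusted p = 0.482 with an estimated correlation). Cytosolic ribosomal proteins lay above it, where 0 of 78 rose (2 adjusted over the list alone), camera adjusted p = 0.00252 (adjusted p = 0.586 with an estimated correlation). The remaining lists gave camera adjusted p from 0.0568 to 0.98, and adjusted p of at least 0.586 with an estimated correlation, and median and mean differed in sign for O-GlcNAc, ribosome biogenesis and stromal lists. Of the called lists, 4 were lost without single libraries. Without control replicate 1, adjusted p was 0.0897 for the BCL2 family, 0.109 for CDKs and cyclins and 0.0899 for NF-kB targets. It was 0.0549 for CDKs and cyclins without OSMI-2 replicate 1, 0.0834 for NF-kB targets without OSMI-2 replicate 2 and 0.377 for the BCL2 family without AT7519 replicate 1. Calls were also lost for NF-kB targets (0.506) and ribosomal proteins (0.0976) without AT7519 replicate 2, and the BCL2 family (0.155) and NF-kB targets (0.106) without combination replicate 1. Of the lists not called, 10 passed without 1 library, the smallest adjusted p being 2.03e-05 for ATF4 targets without OSMI-2 replicate 1.

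**Figure D3:**
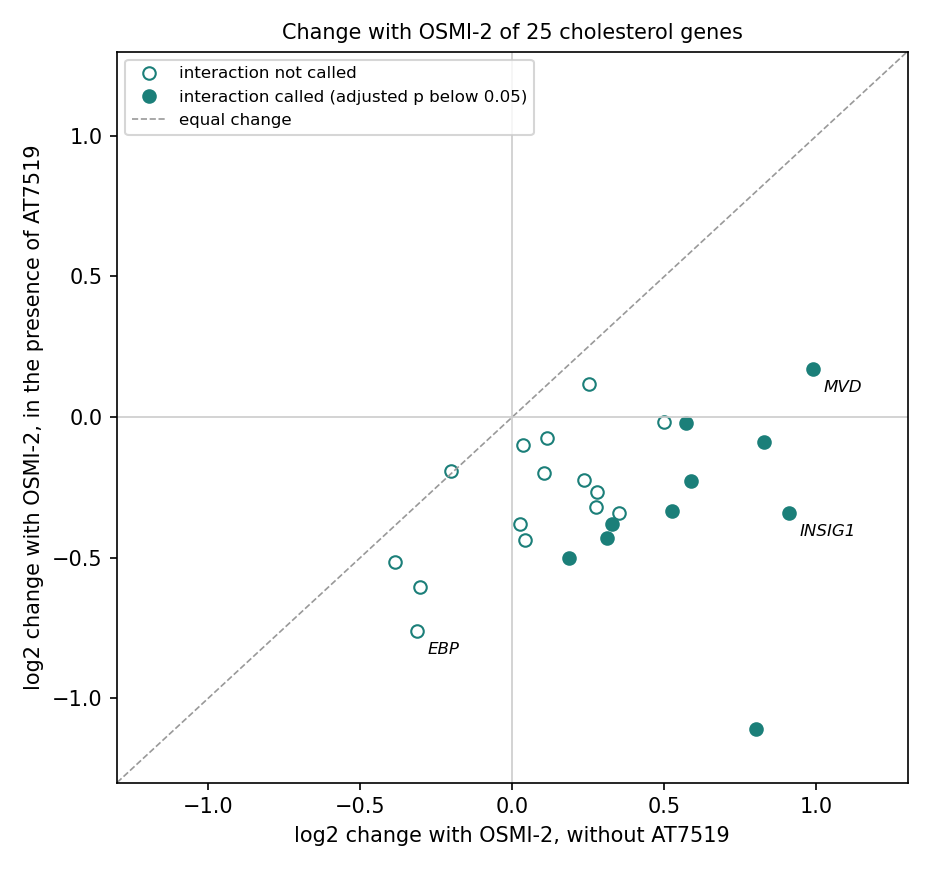
Log2 change with OSMI-2 of the 25 cholesterol genes, without AT7519 (x axis) and with it (y axis), where filled points are the 10 genes called in the interaction and the dashed line marks equal change. Of the 25 points, 24 lie below the line.

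On the deposited scale, genes that passed with OSMI-2 and with AT7519 mostly moved in opposite directions. Scaled to mitochondrial mRNAs this turned over, as 519 genes moved together, 7 up and 512 down, of the 721 called with OSMI-2. On that scale 14496 of the 19393 tested genes fell with AT7519, and 624 of the 721 fell with OSMI-2. Most genes that fell with OSMI-2 would thus fall in both even if the 2 lists were independent. On the deposited scale, of those called in both comparisons, 304 fell with OSMI-2 and rose with AT7519 against 120 if the 2 lists were independent. Of the others, 29 did the reverse against 34, 33 rose in both against 32.5, and 38 fell in both against 125. The changes with OSMI-2 and with AT7519 correlated across genes with r = -0.000474, where simulated data without effects gave 0.471 (0.451 to 0.489 in 50 draws) because both comparisons share the control libraries. Without effects the simulated changes vary less than the real ones, so the 2 values of r cannot be compared directly. The covariance was -0.000163, against 0.0414 (0.0381 to 0.0445) in the simulated data. Sharing control libraries moves both comparisons the same way, as in the simulated data. On the deposited scale the genes moving together showed no clear excess over independent lists. The number of genes moving together, 71 in all, was 51 without control replicate 1, 0 without control replicate 2, 9 without OSMI-2 replicate 1, 2 without OSMI-2 replicate 2, 159 without AT7519 replicate 1 and 100 without AT7519 replicate 2. At the 0 without control replicate 2, limma called 2 genes for OSMI-2, with 1652 at an unadjusted p below 0.05. With an estimated correlation between genes in place of the preset one, camera called none of the lists at an adjusted p of 0.05 in any of the 6 comparisons. That run rests on 4 residual degrees of freedom, so these losses do not by themselves measure correlation between genes. For immediate early genes with AT7519, an estimated correlation of 0.0122 beside the preset 0.01 took the camera p-value from 0.000658 to 0.0292. The lists described first for OSMI-2 had far higher estimates, with 0.736 for G1/S genes, 0.684 for ATF4 targets and 0.39 for ribosome biogenesis genes. The estimates were 0.387 for G2 and M phase genes, 0.313 for chaperones, 0.289 for cholesterol genes and 0.263 for heat shock genes. For these lists, p-values at the preset correlation may be far too small.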

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

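The test of other scalings and the test of whether AT7519 only prevented the rise, both for cholesterol genes, were chosen after the result was seen.

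The effect of OSMI-2 differed between cells with and without AT7519 in 201 genes, by the interaction term. The interaction is the log2 change with OSMI-2 when AT7519 was present minus that when it was absent. It was -1.25 for INSIG1, -2.27 for CYR61, -2.35 for IER5, -2.15 for CITED2, -1.95 for BTG2, -1.68 for BTG1 and -1.94 for MIR17HG. It was -1.54 for PLK2, -1.17 for BBC3, -0.80 for CCNT1, -0.73 for BRD2, -0.61 for DNAJC3, -0.55 for MYC and -0.60 for MCL1. It was above 0 for MGEA5 (0.60), PPP1R10 (1.29), SMAD6 (1.41), XRCC2 (0.79) and ZNF382 (1.07). Of these 19 genes 0 were called without each library in turn. Without control replicate 1, control replicate 2, OSMI-2 replicate 1 or OSMI-2 replicate 2, the number of the 19 kept was 0, 0, 0 and 1, without AT7519 replicate 1 or combination replicate 2 it was 7, and without combination replicate 1 it was 16.

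Cholesterol synthesis and SREBP2 target genes lay below the sum of the single agents, with a median interaction of -0.55 over 25 genes. Camera called the list at the preset correlation, but it did not pass with an estimated correlation (adjusted p = 0.163) or in fry (adjusted p = 0.093). The scaling of the libraries is argued against, since the highest median under 4 other scalings was -0.505. A single library is also argued against, as the highest median without 1 library was -0.459, without control replicate 2. In the combination against AT7519, 10 of the 25 genes fell and 0 rose. For the list as a whole, it cannot be told apart whether AT7519 only prevented the rise seen with OSMI-2 or the genes also fell. The median over genes in the combination against AT7519 was -0.321. The list medians of the libraries differed by -0.294, with a large spread between libraries (SE 0.105). That difference was only -0.196 (SE 0.109) at equal upper quartiles and -0.168 (SE 0.0782) after quantile normalisation. A biological loss of the SREBP2 response in cells with both agents stays open, and no measurement here of protein or sterol level tests it.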

How the results depend on the processing

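The alternatives for genes moving together with OSMI-2 and AT7519, and those that leave a library out of the list tests, were chosen after the results were seen. Unless a sentence says otherwise, the cause of a change was not tested.

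Counts of called genes within 1.5 times the reported ones are not listed. For OSMI-2 against control (586 reported) the count was 101 with no filter, 262 at equal totals, 285 at equal upper quartiles, 0 with limma without the trend (2788 at an unadjusted p below 0.05; edgeR 667), 1412 with the compared groups only, 1509 with DESeq2 and 27 with a change of at least 1. It ran from 2 to 892 when 1 library was left out, with 2 without control replicate 2, 15 without OSMI-2 replicate 2, 117 without OSMI-2 replicate 1, 297 without control replicate 1, 883 without AT7519 replicate 2 and 892 without AT7519 replicate 1. With no filter more genes were tested and the variance trend was refitted over them, and which of these gave fewer calls was not tested. Fewer calls with a change of at least 1 follow from a stricter rule. For AT7519 against control (10323) it was 3058 with a change of at least 1 and ran from 8294 to 10573 without 1 library. For the combination against control (10448) these were 3505 and 8307 to 10861, and against OSMI-2 (10630) 3222 and 8565 to 11066. For the combination against AT7519 (3815) the count was 865 without the trend, 2428 with the compared groups only and 571 with a change of at least 1. It ran from 1683 without combination replicate 2 to 3860, with 2191 without AT7519 replicate 1. For the interaction (201) it was 33 with no filter, 118 at equal upper quartiles, 131 after quantile normalisation, 0 without the trend (1800 at an unadjusted p below 0.05; edgeR 184), 563 with DESeq2 and 72 with a change of at least 1. It ran from 2 to 490 without 1 library, with 4 and 2 without control replicates 1 and 2, 4 and 7 without OSMI-2 replicates 1 and 2, 72 and 490 without AT7519 replicates 1 and 2, and 434 and 55 without combination replicates 1 and 2. With the replicate number as a block, which the labels do not say pairs the libraries, the counts were 865, 10664, 10729, 4295, 10930 and 404 in the order OSMI-2, AT7519, combination against control, AT7519 and OSMI-2, and interaction. Deviations of equal-numbered replicates correlated across genes by 0.035 (control and OSMI-2), 0.021 (control and AT7519), 0.038 (control and combination), 0.034 (OSMI-2 and AT7519), 0.12 (OSMI-2 and combination) and 0.027 (AT7519 and combination).

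Genes moving together with OSMI-2 and AT7519 (71) numbered 7 with no filter, 35 at equal totals, 45 at equal upper quartiles, 132 after quantile normalisation, 519 when scaled to mitochondrial mRNAs, 0 without the trend, 256 with the compared groups only, 136 with the block and 284 with DESeq2. They ran from 0 to 159 without 1 library, with 51 and 0 without control replicates 1 and 2, 9 and 2 without OSMI-2 replicates 1 and 2, and 159 and 100 without AT7519 replicates 1 and 2.

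Of 193 results for named genes, limma without the trend ended 67 calls and no filter 39, pseudocounts of 0.5 and 5 ended 1 and 0, edgeR ended 1 and added 1, and DESeq2 ended 5 and added 3. Directions changed with the scale alone. With AT7519 they turned to log2 changes, scaled to mitochondrial mRNAs, of -0.77 for OGT, -0.13 for CDK9, -0.77 for MYC, -0.43 for MCL1, -0.79 for KLK3, -0.60 for CDKN1A, -0.19 for NELFCD, -0.39 for DUSP1 and -0.29 for KRT8. At equal totals they turned to -0.22 for MYC and -0.041 for CDKN1A, and after quantile normalisation to -0.25 for OGT and -0.52 for KLK3. With the combination against control they turned, scaled to mitochondrial mRNAs, to -0.27 for OGT, -0.89 for MGEA5, -0.64 for CDK9, -0.45 for KLK3, -0.42 for KLF10, -0.24 for GDF15, -0.15 for KLK2 and -0.039 for PHGDH. They turned at equal totals to -0.20 for MGEA5, and after quantile normalisation to -0.20 for MGEA5 and -0.080 for KLK3. In the combination against OSMI-2, scaled to mitochondrial mRNAs, CDK1 turned to -0.20 and BIRC5 to -0.30. The reversals on the mitochondrial scale go with its shift of the median gene, by -0.897 with AT7519 and -0.923 with the combination against control. Which scale is closer to the true levels was not tested.

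Of 140 results for lists, an estimated correlation ended 69 calls, and fry ended 28 and added 8. Fry on the mitochondrial scale, which changes the test and the scale together, gave the opposite direction in 30. In the combination against control, fry on the deposited scale already gave the opposite direction for the fatty acid, interferon and luminal lists. The cause was not tested. On the mitochondrial scale fry had adjusted p for OSMI-2 of 0.671 for zinc finger genes and 0.945 for luminal markers. For AT7519 it was 0.00236 for the O-GlcNAc and the fatty acid lists, 0.00227 for CDKs and cyclins, 0.0017 for chaperones, cholesterol, interferon and luminal lists, 0.0041 for heat shock, 0.00653 for NRF2, and 0.00439 for ribosome biogenesis. It was 0.00749 for splicing, 0.539 for ribosomal proteins, 0.216 for oxidative phosphorylation, 0.0169 for histones and 0.0108 for stromal markers. For the combination against control it was 0.00143 for O-GlcNAc, 0.00754 for ATF4, 0.000666 for chaperones and luminal markers, 0.00283 for NRF2 and splicing, and 0.000711 for fatty acid synthesis. It was 0.000672 for interferon, 0.0995 for ribosomal proteins, 0.0141 for oxidative phosphorylation, 0.0112 for histones and 0.0184 for stromal markers, and against OSMI-2 it was 0.0125 for splicing. Without OSMI-2 replicate 2, camera gave the opposite direction in the interaction for ATF4 targets (adjusted p = 0.00942, range 2.03e-05 to 0.689 without 1 library) and G1/S genes (0.00528, range 7.24e-05 to 0.957).

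Depth limits genes near 3 reads, 1.76 to 5.47 normalised counts, where falls with AT7519 or the combination are given as levels.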

Other observations

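Small RNA genes rose with AT7519. Of 356 tested, 175 rose and 19 fell, with a median log2 change of 1.01, which was 0.688 at equal totals and 0.166 when scaled to mitochondrial mRNAs. Small nucleolar RNAs moved most by median, with 87 of 139 higher and 4 lower (median 1.57), followed by small nuclear RNAs with 28 of 65 higher and 5 lower (1.11), miscellaneous RNAs with 22 of 41 higher and 1 lower (0.888), small Cajal body RNAs with 7 of 14 higher (0.768) and microRNA genes with 31 of 97 higher and 9 lower (0.24). With the combination 195 rose and 26 fell against control, whereas OSMI-2 alone raised 1 and lowered 3.

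By median, small RNA genes rose more than the counts of the genes that host them. Over 260 small RNA genes inside 207 tested hosts, the median difference from the host was 1.27 (SE 0.114), and 206 lay above the host. That argues against a rise of the host counts as the source. It cannot show whether reads of unspliced host RNA were counted for small RNA genes. Of 10000 lists of protein-coding genes matched on mean value, 0 reached the median of the small RNA genes, the highest being -0.0319. The matching used all 8 libraries, among them those with AT7519, so matched genes need not be as low in control. It therefore cannot decide whether low values were pushed up in the AT7519 libraries. The filter, on the same mean, can also admit genes low in control only because they rose. A share of RNA outside messenger RNA that grew as messenger RNA fell could give such a rise and was not tested, and neither was a difference in the size of the fragments sequenced.

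Among 13334 protein-coding genes, the median log2 change with AT7519 was -0.203 in 244 genes with 1 exon and -0.439 in 395 genes with 2. It was -0.0511 with 3 to 5 exons, 0.0716 with 6 to 10, 0.0186 with 11 to 20 and -0.0488 with more than 20. The share that fell was 38.5% and 47.1% with 1 and 2 exons, and 33.9%, 27.4%, 28.1% and 31.3% in the other groups in that order. By gene span, the medians were 0.204, 0.146, 0.0322, -0.124 and -0.19 from the shortest to the longest of 5 equal groups. The differences between these groups were not tested.

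A short span by itself is argued against as the source of the lower median of single-exon genes. Genes with more exons and a span as short had a median higher by 0.647 (SE 0.0925). They were not matched on mean value or kind of gene, so that gap cannot be put down to exon number. Lower values of single-exon genes stay open: 748 of 10000 lists of genes with more exons, matched on mean value, had a median as low, the lowest being -0.345. A shorter life of the transcripts of single-exon genes may also play a part and was not tested.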
